A study of Mus musculus with 9 samples.

How the data were processed

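RNA sequencing libraries came from macrophages sorted from testis, epididymis and brain of C57BL/6J mice, 3 libraries per organ, 9 in all. Per the labels' protocols, tissue was digested with collagenase and DNase for 40 minutes, cells were enriched on Percoll, and live CD45+ CD11b+ F4/80+ Ly6C- CD11c- cells were sorted. Per the same protocols, libraries were made from 10 ng of RNA with a TruSeq RNA v2 kit, which does not mark the strand. The protocol's wording on pooling testis and epididymis suspensions leaves open whether the organs were mixed at any step, and the labels were taken as they stand. All 9 columns of values were matched to a library through the sample number in its title. The labels give no link between libraries of different organs, and replicates are numbered here in the order of the sample list.

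The signal values in the deposited table were made by the authors as reads per gene divided by a factor per library, with the tools listed as CASAVA 1.8, Bowtie2 2.2.1, Partek 6.6 and DESeq2 per the submitters' processing notes. Those notes also name the mm10 genome. The role of each tool, the counting rule and the gene annotation are not given in the sources used here. In every library, 100% of the values were whole multiples of its smallest value above 0, with a largest deviation of 3.9e-10 reads, so whole reads were recovered by division. The factors of the libraries equalled median-ratio size factors recomputed from those reads, with a largest relative difference of 4.7e-15. Rescaling by the median ratio therefore changes next to nothing, and was run only because it had been planned.

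The table holds 15434 genes, of which 15252 matched a GENCODE M21 symbol, 40 a RefSeq symbol, 82 a RefSeq synonym and 60 no reference name, and all were kept. Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 denotes. They place genes and were not used in any test of expression. Genes whose exons overlap another gene, and members of families of near-identical copies, are uncertain because the kit does not mark the strand and the treatment of shared reads is unknown.

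Libraries held between 2727092 and 4458688 reads assigned to genes. Between 10551 and 12302 genes had a value above 0 in a library, and 1 read corresponded to between 0.808 and 1.11 normalised reads. Mitochondrially encoded genes took between 0.421% and 0.769% of reads, or between 0.393% and 0.571% without COX2 and ATP6, chosen after their values were seen, which were near 0 in some libraries of an organ and high in others. Malat1 was the highest gene in 8 libraries, with 2.47% to 4.12% of reads, and Apoe in epididymis replicate 3, with 3.51%. Variation between replicates exceeded counting error, and a common biological coefficient of variation of 0.913 was estimated by edgeR on the recovered reads.

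Values were analysed as log2(value + 1). Genes with a value of at least 10 in at least 3 libraries were tested, 11766 in all. A linear model with 1 mean per organ was fitted over the 9 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level (6 residual and 9.08 prior degrees of freedom). The 3 pairwise contrasts and a moderated F test over the organs were each adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Where an organ had no read, folds were bounded by 3 reads per library, and with 1 to 3 reads in an organ an exact 95% interval of the ratio of read rates was computed.

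Before the data were examined, 33 gene lists were fixed, for macrophage states, microglia, shared processes and other cell types of the organs. The 31 lists with at least 3 tested members were tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted by the Benjamini-Hochberg method over lists and comparisons, and again with a correlation estimated per list. Members were also adjusted over the list alone. The lists of mast cells, basophils and eosinophils and of erythroid cells had 1 and 2 tested members and were not tested.

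Genes were named by a rule written before the data were examined. In each comparison the rule took the 10 largest folds in each direction among called genes whose 3 libraries of one organ lay above all 3 of the other, with a mean in the higher organ of at least 110, the median over tested genes of the highest organ mean. Provisional and small RNA symbols were left out. It added up to 3 called members of each list in each direction, and the sort markers Ptprc, Itgam, Adgre1, Itgax and Ly6c2. Only part of these genes is printed, and genes outside the rule are marked as chosen after their values were seen.

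The procedure was tested on simulated data with the depths and dispersions of these libraries, in 5 simulations of 11766 genes with 200 changed. At a 2-fold change limma called 3.88% of changed genes, at 4-fold 26.9% and at 16-fold 50.3%, with 17 calls among 52912 unchanged genes. Corresponding values for edgeR 4.0.16 were 2.69%, 23% and 52.1%, with 8 calls. Of 5 lists of 20 genes raised 4-fold, camera gave an unadjusted p below 0.05 for 5, and of 5 unchanged lists for 0. Genes were drawn independently, so these lists do not test camera where members are correlated.

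Alternatives planned before the data were examined were other pseudocounts (0.1 and 5), no filter and a stricter filter, rescaling to the same total and by the median ratio, quantile normalization, moderation without trend and with robust variances, library weights, fits of only 2 organs, a minimum fold of 2, fry and an estimated correlation for lists, and leaving out each library. Chosen after seeing the data were the quasi-likelihood test of edgeR and DESeq2 1.42.0, both on the recovered reads. Calls were compared with those for other splits of the libraries, and overlaps were simulated 20 times with no gene changed in any library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Sequencing reads were not used here.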

Results

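Gene expression was measured by RNA sequencing in macrophages sorted from the testis, the epididymis and the brain of C57BL/6J mice, with 3 libraries per organ and no culture or treatment. The epididymis is the duct in which sperm mature after leaving the testis, and the brain cells are named microglia in the library titles. The sort kept live cells that carried CD45, CD11b and F4/80 and lacked Ly6C and CD11c. The series title concerns the embryonic origin of the macrophages that reside in testis and epididymis, while the libraries themselves compare organs. The table holds 15434 genes. The testis libraries held 3383929, 4458688 and 4170640 reads assigned to genes, the epididymis libraries 3482167, 3326780 and 2966349, and the brain libraries 3214329, 2727092 and 3516387. Values below are normalised read counts, given as mean ± SD of 3 libraries. The labels give 1 mouse number for the 3 libraries of an organ, a different one for each organ, and do not say that the libraries came from separate animals. Organ and mouse number therefore cannot be separated in any comparison, and p-values measure only the spread between these libraries, which may be technical.

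On the first 2 principal components the libraries of each organ lay apart from the others. Component 3 (14.2% of the variance) instead set testis replicate 1 (99.13) and epididymis replicate 3 (97.16) apart from the other libraries of their organs. Across the tested genes, Pearson's r of log2 values lay between 0.787 and 0.832 among brain libraries, between 0.676 and 0.698 among epididymis libraries and between 0.695 and 0.76 among testis libraries. Between organs it lay between 0.556 and 0.703, where genes are not independent replicates. These correlations did not set the epididymis apart, since epididymis replicate 1 reached 0.703 with brain replicate 3 and 0.687 with testis replicate 2. Of 11766 genes tested, 1337 differed among the 3 organs by limma's moderated F test at a Benjamini-Hochberg adjusted p below 0.05. That count was 859 without brain replicate 1 and 737 without the trend of the variance on the mean level.

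**Figure D1:**
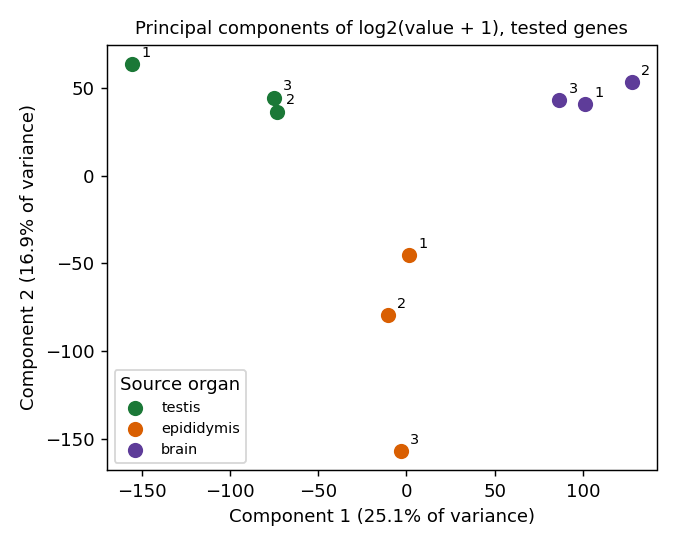
Principal components of log2(value + 1) over the tested genes, with 1 point per library, coloured by organ and numbered by replicate. The horizontal axis (25.1% of the variance) separates testis (-155.3 to -73.25), epididymis (-10.27 to 1.513) and brain (86.66 to 127.5), and the vertical axis (16.9%) sets the epididymis libraries below the others.

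The comparison of testis with epididymis is the one named by the series title. Genes known from microglia were lower in testis macrophages. Fcrls, an Fc receptor-like gene of microglia, stood at 116 ± 52.8 in testis and 1219 ± 270 in epididymis (log2 fold -3.49, SE 0.33, limma adjusted p = 4.9e-05). Trem2, a lipid-sensing receptor of macrophages, stood at 479 ± 70.5 and 2108 ± 360 (log2 fold -2.13, SE 0.20, limma adjusted p = 4.9e-05). Ccr2, the chemokine receptor that monocytes use to leave the bone marrow, went the other way, at 1343 ± 197 in testis and 45.3 ± 27.7 in epididymis (log2 fold 5.11, SE 0.52, limma adjusted p = 5.3e-05). The list of 13 tested monocyte genes was not called, with 2 higher in testis and 11 not passed (limma's camera adjusted p = 0.066, and adjusted p = 0.49 with an estimated correlation), or 4 higher when adjusted over the list alone. Testis libraries also carried the lectin gene Mgl2 at 1752 ± 164 against 17.8 ± 21.6, and the scavenger receptor gene Cd163l1 at 686 ± 206 against 1.21 ± 2.1. T and NK cell transcripts were higher in the same testis libraries, and which cells gave the reads of Ccr2, Mgl2 and Cd163l1 was not tested.

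Of 18 tested genes on the list for microglia identity, 10 fell in testis relative to epididymis, 1 rose and 7 did not pass. Adjusted over the list alone, 11 fell and 1 rose. The list as a whole was lower by limma's camera (adjusted p = 1.3e-09, and adjusted p = 0.011 with an estimated correlation). Besides Fcrls and Trem2, the transcription factor gene Bhlhe41 fell from 714 ± 68.2 in epididymis to 111 ± 44.2 in testis. Olfml3 stood at 640 ± 238 in epididymis and 35.9 ± 29.1 in testis, and the purinergic receptor gene P2ry13 at 369 ± 83.0 and 31.7 ± 33.0, with limma adjusted p of 0.0016 and 0.0018, or 0.072 and 0.062 without the variance trend. Tmem119, chosen after its values were seen, stood at 234 ± 101 in testis and 1423 ± 127 in epididymis. The member that rose was Sparc, a matrix-binding protein gene, at 459 ± 220 in testis and 81.8 ± 12.2 in epididymis. On GRCm38, Fcrls lies on chromosome 3 from 87250758 to 87263738, Trem2 on chromosome 17 from 48346401 to 48354147, Tmem119 on chromosome 5 from 113793729 to 113800516 and Ccr2 on chromosome 9 from 124101950 to 124113557.

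Immediate early and dissociation stress genes were higher in testis. Of 20 tested, 16 rose and 4 did not pass, and 18 rose when adjusted over the list alone (limma's camera adjusted p = 1.2e-21, and adjusted p = 0.04 with an estimated correlation). Dusp1, a phosphatase gene induced within minutes of cell stress, stood at 4441 ± 972 in testis and 1027 ± 290 in epididymis. Hspa1a, an inducible heat shock protein gene chosen after its values were seen, stood at 60720 ± 3750 and 17190 ± 973. Its copy Hspa1b is nearly identical in sequence, so reads may be split between the pair. Without the variance trend the limma adjusted p was 0.062 for Dusp1 and 0.071 for Hspa1a. Of 26 ribosomal protein genes, 18 rose in testis and 8 did not pass, and 22 rose when adjusted over the list alone (limma's camera adjusted p = 7.9e-22, and adjusted p = 0.045 with an estimated correlation). Rpl13 stood at 1241 ± 38.3 in testis and 386 ± 174 in epididymis (limma adjusted p = 0.0052, or 0.11 without the variance trend). Ribosomal protein genes have many processed pseudogenes that can share reads with them.

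For 3 lists of macrophage genes the call depended on the correlation assumed. Of 19 tested sort-gate and pan-macrophage genes, 5 fell in testis and 14 did not pass, while adjusted over the list alone 5 fell and 2 rose (limma's camera adjusted p = 0.00088, but adjusted p = 0.097 with an estimated correlation). Itgam, which encodes CD11b, stood at 361 ± 84.9 in testis and 1094 ± 176 in epididymis, and Mertk, a receptor for apoptotic cells, at 378 ± 149 and 1168 ± 305. Their limma adjusted p was 0.00097 and 0.0037, or 0.077 and 0.13 without the variance trend. Ptprc, which encodes CD45, stood at 2805 ± 478 and 2944 ± 512, Adgre1, which encodes F4/80, at 191 ± 78.2 and 454 ± 199, and Ly6c2 at 81.6 ± 19.3 and 11.1 ± 18.4, none of which passed. Itgax, which encodes the CD11c that the sort excluded, stood at 256 ± 43.3 in epididymis and 7.12 ± 12.3 in testis (limma adjusted p = 0.027, and up to 0.11 when testis replicate 2 was left out). Of 17 tested efferocytosis and scavenger receptor genes, 5 fell in testis and 12 did not pass, and 7 fell when adjusted over the list alone (limma's camera adjusted p = 0.00011, but adjusted p = 0.089 with an estimated correlation). Abca1, a cholesterol exporter gene, stood at 474 ± 211 and 1806 ± 173, with a limma adjusted p of 0.0014, or 0.079 without the variance trend. Of 17 tested anti-inflammatory genes, 3 fell, 1 rose and 13 did not pass, while adjusted over the list alone 4 fell and 1 rose (limma's camera adjusted p = 0.027, but adjusted p = 0.11 with an estimated correlation). That list's call was lost in 3 of 9 leave-outs, with an adjusted p of up to 0.069 without testis replicate 2. As lists, Lyve1-type (limma's camera adjusted p = 0.14), type I interferon (0.35), MHC class II (0.37), inflammatory (0.64) and cell division genes (0.78) were not called between testis and epididymis. Single members of the Lyve1-type, MHC class II and inflammatory lists passed in both directions. The lack of a call does not show equal levels.

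**Figure D2:**
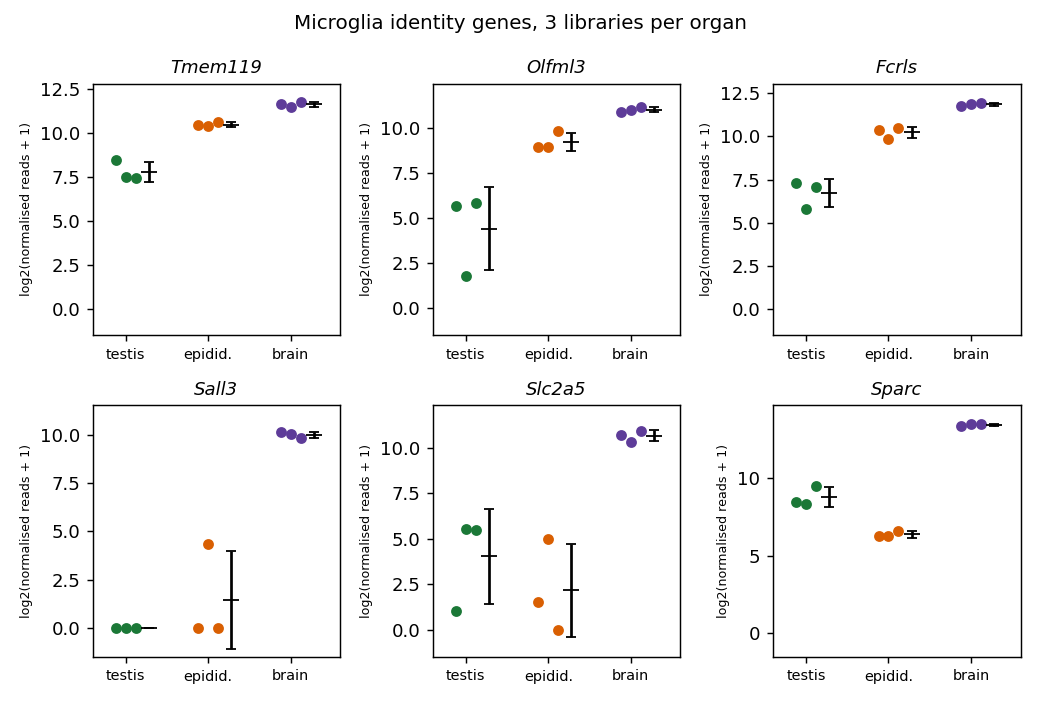
Values of 6 genes of the microglia identity list as log2(normalised reads + 1), with 1 point per library and the mean ± SD of 3 libraries beside them. Tmem119, Olfml3 and Fcrls in epididymis lie between testis and brain, while Sall3, Slc2a5 and Sparc have epididymis means of 6.57, 10.9 and 81.8 normalised reads.

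Transcripts of other cell types differed between the same libraries. Of 9 tested Leydig cell and steroidogenesis genes, 5 rose in testis and 4 did not pass, and 6 rose when adjusted over the list alone (limma's camera adjusted p = 4.5e-07, and adjusted p = 0.026 with an estimated correlation). Insl3, a peptide hormone gene of Leydig cells, stood at 1117 ± 740 in testis and 0 in epididymis, at least 382-fold higher against a floor of 3 reads per library, and such floors and intervals cover counting error only. Cyp17a1, a steroid hydroxylase gene, stood at 344 ± 52.4 against 0, at least 118-fold higher. Insl3 lies on chromosome 8 from 71689214 to 71690575 and shares exonic sequence with Jak3, and Cyp17a1 on chromosome 19 from 46667165 to 46673172. The Leydig list took 8.03 ± 3.52 of every 10000 reads in testis, 0.909 ± 0.329 in epididymis and 0.87 ± 0.171 in brain. Of 9 tested T and NK cell genes, 4 rose in testis and 5 did not pass, and 7 rose when adjusted over the list alone (limma's camera adjusted p = 1.3e-05, and adjusted p = 0.026 with an estimated correlation). That list took 3.46 ± 0.471 of every 10000 reads in testis and 0.491 ± 0.194 in epididymis. Of 4 tested genes of the epididymal epithelium, 2 fell in testis and 2 did not pass, also when adjusted over the list alone (limma's camera adjusted p = 0.0058, but adjusted p = 0.086 with an estimated correlation). Defb20, a beta-defensin gene, stood at 217 ± 72.0 in epididymis and 0 in testis, at least 80.4-fold lower, and belongs to a family whose copies can share reads.

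In this comparison 516 of 11766 genes passed limma's test, 293 higher and 223 lower in testis, and 2060 had an unadjusted p below 0.05. The balance turned to 227 higher and 307 lower when libraries were rescaled to the same total, and to 223 higher and 256 lower after quantile normalization. The 3 values of one organ lay entirely apart from those of the other in 19.8% of tested genes, against 10% by chance. Of the genes called, 93 had 3 or fewer reads in all libraries of 1 organ together. The count was 301 without testis replicate 2, 278 without epididymis replicate 2, 293 without epididymis replicate 3, 192 without the variance trend and 250 with only these 6 libraries in the fit. DESeq2 on the recovered reads, an alternative chosen after seeing the data, called 782.

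Against brain, all 18 tested microglia identity genes fell in testis. Of 15 tested MHC class II genes, 7 rose, 1 fell and 7 did not pass, and the call of the list as a whole was lost with an estimated correlation (limma's camera adjusted p = 0.16). Sall3, a zinc finger transcription factor gene, had no read in testis and stood at 1040 ± 111 in brain, at least 386-fold lower. H2-Aa, an MHC class II chain gene, stood at 14600 ± 1800 in testis and 59.4 ± 13.2 in brain (log2 fold 7.93, SE 0.22, limma adjusted p = 5.9e-12). Slamf7, an immune cell receptor gene, stood at 928 ± 94.0 and 3.19 ± 3.11 (log2 fold 8.20, SE 0.69, limma adjusted p = 1.2e-06). Nav3 had the reverse pattern, at 1.69 ± 2.27 in testis and 1788 ± 157 in brain (log2 fold -9.72, SE 1.27, limma adjusted p = 9.9e-05). Sall3 lies on chromosome 18 from 80966376 to 80986771, H2-Aa on chromosome 17 from 34282744 to 34287823, and Nav3 on chromosome 10 from 109681259 to 110456204. Slamf7 lies on chromosome 1 from 171632403 to 171653035, where its exons overlap a gene on the opposite strand.

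The microglia identity list was lower by limma's camera (adjusted p = 1.8e-27, and adjusted p = 0.0019 with an estimated correlation), and all 18 members also fell when adjusted over the list alone. Slc2a5, a fructose transporter gene, stood at 30.5 ± 25.5 in testis and 1642 ± 339 in brain, and Crybb1 at 0 and 139 ± 38.4. Siglech fell from 2702 ± 260 in brain to 147 ± 39.9 in testis. The MHC class II list had a limma camera adjusted p of 3.6e-05 with the preset correlation, and adjusted over the list alone 8 of its members rose and 3 fell. Cd74, the invariant chain gene, stood at 3648 ± 566 in testis and 24.5 ± 19.8 in brain. The member that fell in the main test was Ctss, a lysosomal protease gene, at 5059 ± 2390 and 8717 ± 1220, whose limma adjusted p of 0.045 rose to 0.2 without testis replicate 1. Of 12 tested genes of Lyve1-type tissue macrophages, 6 rose and 6 did not pass, while adjusted over the list alone 7 rose and 1 fell (limma's camera adjusted p = 2.6e-05, but adjusted p = 0.078 with an estimated correlation). Pf4, a platelet chemokine gene that is also expressed by tissue macrophages, stood at 985 ± 443 in testis and 1.82 ± 3.16 in brain, and Cbr2 at 190 ± 135 and 0.

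Of 18 tested type I interferon response genes, 7 rose in testis against brain and 11 did not pass, and 10 rose when adjusted over the list alone (limma's camera adjusted p = 1.8e-05, and adjusted p = 0.026 with an estimated correlation). Ifit3, an interferon-induced gene, stood at 189 ± 19.9 in testis and 9.26 ± 8.91 in brain. Of 17 tested cell division genes, 5 rose and 12 did not pass, and 6 rose when adjusted over the list alone (limma's camera adjusted p = 0.00059, and adjusted p = 0.041 with an estimated correlation). Mki67, a proliferation marker gene, stood at 161 ± 68.3 and 2.12 ± 3.68. Of 26 ribosomal protein genes, 23 rose and 3 did not pass, also when adjusted over the list alone (limma's camera adjusted p = 4.6e-29, and adjusted p = 0.034 with an estimated correlation), with Rpl23 at 23760 ± 1810 and 3660 ± 702. Of 20 tested inflammatory cytokine and chemokine genes, 5 rose, 1 fell and 14 did not pass, while adjusted over the list alone 9 rose and 2 fell (limma's camera adjusted p = 0.00033, but adjusted p = 0.13 with an estimated correlation). The neutrophil attractant gene Cxcl2 stood at 12810 ± 11200 in testis and 117 ± 65.6 in brain, with most of the testis mean from replicate 3 (25750, against 6595 and 6098 in replicates 1 and 2). Of 13 tested monocyte genes, 4 rose and 9 did not pass, also when adjusted over the list alone (limma's camera adjusted p = 0.013, but adjusted p = 0.38 with an estimated correlation, and 0.051 without testis replicate 2), with S100a6 at 1816 ± 709 and 27.9 ± 16.2. Of 20 immediate early and dissociation stress genes, 11 rose, 1 fell and 8 did not pass, while adjusted over the list alone 14 rose and 2 fell (limma's camera adjusted p = 2.1e-07, but adjusted p = 0.17 with an estimated correlation).

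Efferocytosis and scavenger receptor genes went both ways in testis against brain, with 3 higher, 4 lower and 10 not passed of 17 tested, and 3 higher and 6 lower when adjusted over the list alone. Axl, a receptor tyrosine kinase gene for apoptotic cell uptake, stood at 502 ± 167 in testis and 3.56 ± 5.4 in brain, while its relative Mertk stood at 378 ± 149 and 5231 ± 1200. The scavenger receptor gene Cd36 stood at 410 ± 195 and 3.56 ± 5.4. The list's median log2 fold was -1.16 and its mean 0.06, of opposite sign. It was called lower by limma's camera (adjusted p = 0.041, but adjusted p = 0.33 with an estimated correlation), and the call held in 5 of 9 leave-outs, with an adjusted p of up to 0.15 without brain replicate 3. It was also lost when libraries were rescaled to the same total (0.051) and after quantile normalization (0.059).

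Of 13 tested germ cell genes, 9 rose in testis against brain and 4 did not pass, and 10 rose when adjusted over the list alone (limma's camera adjusted p = 4.7e-07, and adjusted p = 0.023 with an estimated correlation). Prm1, a protamine gene that packs sperm DNA, stood at 316 ± 256 in testis, 161 ± 133 in epididymis and 0 in brain. The germ cell list took 5.95 ± 1.81 of every 10000 reads in testis, 3.68 ± 0.838 in epididymis and 1.16 ± 0.114 in brain. Of 9 tested Leydig genes, 4 rose and 5 did not pass, and 6 rose when adjusted over the list alone (limma's camera adjusted p = 4.2e-05, and adjusted p = 0.043 with an estimated correlation). Of 9 tested T and NK cell genes, 7 rose and 2 did not pass, and 8 rose when adjusted over the list alone (limma's camera adjusted p = 5.1e-06, and adjusted p = 0.026 with an estimated correlation). Il2rb, an interleukin receptor chain gene, had 1 read over the brain libraries and stood at 293 ± 43.4 in testis, a ratio of reads of 903 with a 95% counting interval of 162 to 35700. Of 7 tested fibroblast and smooth muscle genes, 3 rose and 4 did not pass, and 4 rose when adjusted over the list alone (limma's camera adjusted p = 0.012, but adjusted p = 0.2 with an estimated correlation).

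**Figure D3:**
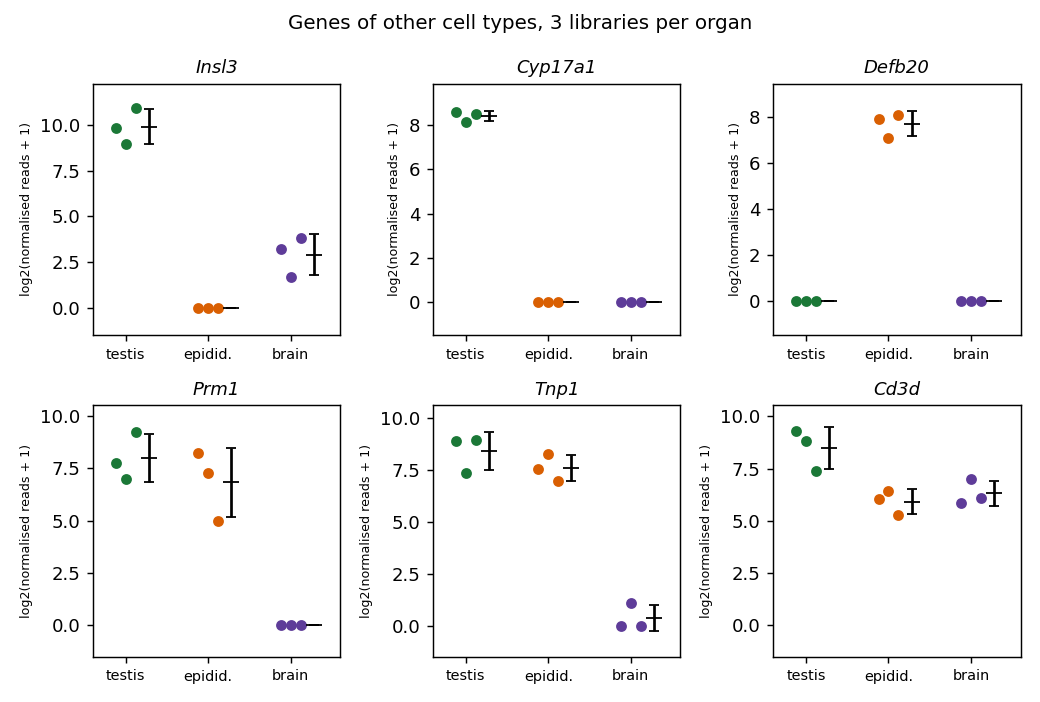
Values of 6 genes of other cell types as log2(normalised reads + 1), with 1 point per library and the mean ± SD of 3 libraries beside them. Insl3 and Cyp17a1 belong to the Leydig list, Defb20 to the epididymal epithelium, Prm1 and Tnp1 to germ cells and Cd3d, chosen after its values were seen, to T and NK cells, where Cd3d stood at 419 ± 235 normalised reads in testis, 63.2 ± 24.4 in epididymis and 84.0 ± 37.8 in brain.

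Testis and brain differed in 1371 of 11766 genes by limma's test, 803 higher and 568 lower in testis, with 2754 at an unadjusted p below 0.05 and 30.8% of genes with no overlap of values against 10% by chance. The balance turned to 654 higher and 772 lower when libraries were rescaled to the same total. Of the genes called, 238 had 3 or fewer reads in all libraries of 1 organ together. The count was 827 without brain replicate 1, 889 without brain replicate 2 and 837 without the variance trend. Among the sort markers, Itgam stood at 361 ± 84.9 in testis and 2197 ± 221 in brain (log2 fold -2.62, SE 0.23, limma adjusted p = 2e-06). Ptprc stood at 2805 ± 478 and 1622 ± 247, with a limma adjusted p of 0.021 that reached 0.089 without testis replicate 2. Its call was also lost when libraries were rescaled to the same total and after quantile normalization. Adgre1 stood at 191 ± 78.2 and 71.7 ± 25.5, Ly6c2 at 81.6 ± 19.3 and 20.4 ± 22.9 and Itgax at 7.12 ± 12.3 and 0, none of which passed.

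Against brain, 12 of 18 tested microglia identity genes fell in epididymis and 6 did not pass. Of 15 tested MHC class II genes, 6 rose and 9 did not pass, and the call of the list as a whole was lost with an estimated correlation (limma's camera adjusted p = 0.081). H2-Aa stood at 4982 ± 894 in epididymis and 59.4 ± 13.2 in brain (log2 fold 6.38, SE 0.22, limma adjusted p = 1.5e-10). Axl stood at 756 ± 66.6 and 3.56 ± 5.4 (log2 fold 8.11, SE 0.76, limma adjusted p = 1e-05), and Clec12a, an inhibitory lectin receptor gene of myeloid cells, at 794 ± 82.2 and 6.31 ± 5.66 (log2 fold 7.38, SE 0.73, limma adjusted p = 1.8e-05). Adamts1, a secreted metalloprotease gene, had no read in epididymis and stood at 1832 ± 459 in brain, at least 626-fold lower. Apoe, an apolipoprotein gene chosen after its values were seen, stood at 105700 ± 5580 in epididymis, 803 ± 148 in brain and 5919 ± 2740 in testis. Axl lies on chromosome 7 from 25757273 to 25788705, Clec12a on chromosome 6 from 129342691 to 129365303, and Adamts1 on chromosome 16 from 85793827 to 85803113.

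The microglia identity list was lower in epididymis by limma's camera (adjusted p = 4.3e-19, and adjusted p = 0.0029 with an estimated correlation), and 17 of its members fell when adjusted over the list alone. Sall1, a transcription factor gene of microglia on chromosome 8 from 89027235 to 89044162, stood at 10.1 ± 17.4 in epididymis and 660 ± 143 in brain. Sall3 stood at 6.57 ± 11.4 and 1040 ± 111, and Slc2a5 at 10.9 ± 17.4 and 1642 ± 339. Trem2, at 2108 ± 360 and 3220 ± 119, did not pass. The MHC class II list had a limma camera adjusted p of 1.9e-08 with the preset correlation, and 7 of its members rose when adjusted over the list alone. Of 18 tested type I interferon response genes, 7 rose and 11 did not pass, and 12 rose when adjusted over the list alone (limma's camera adjusted p = 8e-10, and adjusted p = 0.011 with an estimated correlation). Ifit2 stood at 359 ± 24.4 in epididymis and 14.4 ± 20.5 in brain. Of 17 tested cell division genes, 3 rose and 14 did not pass, also when adjusted over the list alone (limma's camera adjusted p = 0.00022, and adjusted p = 0.038 with an estimated correlation). Mki67 stood at 129 ± 99.2 and 2.12 ± 3.68, with a limma adjusted p of 0.009 that reached 0.062 without epididymis replicate 1.

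Of 12 tested Lyve1-type genes, 3 rose in epididymis against brain and 9 did not pass, while adjusted over the list alone 5 rose and 1 fell (limma's camera adjusted p = 4.1e-05, but adjusted p = 0.081 with an estimated correlation). Mrc1, the mannose receptor gene, stood at 1631 ± 102 and 64.1 ± 20.6, and Igf1, a growth factor gene, at 340 ± 49.0 and 18.3 ± 12. Of 20 tested inflammatory genes, 5 rose, 1 fell and 14 did not pass, while adjusted over the list alone 6 rose and 1 fell (limma's camera adjusted p = 5.9e-05, but adjusted p = 0.098 with an estimated correlation), with Cxcl16 at 2004 ± 271 and 156 ± 14.5. Of 19 tested sort-gate and pan-macrophage genes, 5 rose, 2 fell and 12 did not pass, while adjusted over the list alone 7 rose and 4 fell (limma's camera adjusted p = 0.015, but adjusted p = 0.19 with an estimated correlation). Lyz2, the lysozyme gene of macrophages, stood at 2298 ± 1030 and 284 ± 125. Itgax stood at 256 ± 43.3 in epididymis and 0 in brain, at least 88.0-fold higher. Adgre1 stood at 454 ± 199 and 71.7 ± 25.5 (limma adjusted p = 0.005, or 0.051 without the variance trend). Ptprc stood at 2944 ± 512 and 1622 ± 247 (limma adjusted p = 0.025, and up to 0.11 without epididymis replicate 3) and Itgam at 1094 ± 176 and 2197 ± 221 (limma adjusted p = 0.02, and up to 0.099 without brain replicate 2). Ly6c2 did not pass, at 11.1 ± 18.4 and 20.4 ± 22.9. Of 26 ribosomal protein genes, 8 rose and 18 did not pass, and 17 rose when adjusted over the list alone (limma's camera adjusted p = 5.3e-14, but adjusted p = 0.089 with an estimated correlation). Of 20 stress genes, 4 fell, 1 rose and 15 did not pass, while adjusted over the list alone 7 fell and 1 rose (limma's camera adjusted p = 0.00091, but adjusted p = 0.39 with an estimated correlation), with Egr1 at 1646 ± 371 in epididymis and 8567 ± 2060 in brain.

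Germ cell and epididymal epithelium lists were higher in epididymis than in brain. Of 13 tested germ cell genes, 6 rose in epididymis against brain and 7 did not pass, also when adjusted over the list alone (limma's camera adjusted p = 2.5e-06, and adjusted p = 0.026 with an estimated correlation). Tnp1, a transition protein gene of spermatids, had 1 read over the brain libraries and stood at 203 ± 89.8 in epididymis, a ratio of reads of 642 with a 95% counting interval of 115 to 25400. Of 4 tested genes of the epididymal epithelium, 2 rose and 2 did not pass, also when adjusted over the list alone (limma's camera adjusted p = 0.00022, and adjusted p = 0.041 with an estimated correlation). Adam7, a sperm maturation gene of the epididymis, stood at 194 ± 92.0 in epididymis and 0 in brain, at least 66.6-fold higher. The epithelial list took 2.32 ± 0.499 of every 10000 reads in epididymis, 0.212 ± 0.159 in testis and 0.0203 ± 0.0239 in brain.

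Epididymis and brain differed in 564 of 11766 genes by limma's test, 352 higher and 212 lower in epididymis, with 1925 at an unadjusted p below 0.05 and 22% of genes with no overlap of values against 10% by chance. Of the genes called, 99 had 3 or fewer reads in all libraries of 1 organ together. The count was 320 without brain replicate 1, 327 without brain replicate 2, 306 without the variance trend and 904 with DESeq2 on the recovered reads.

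**Figure D4:**
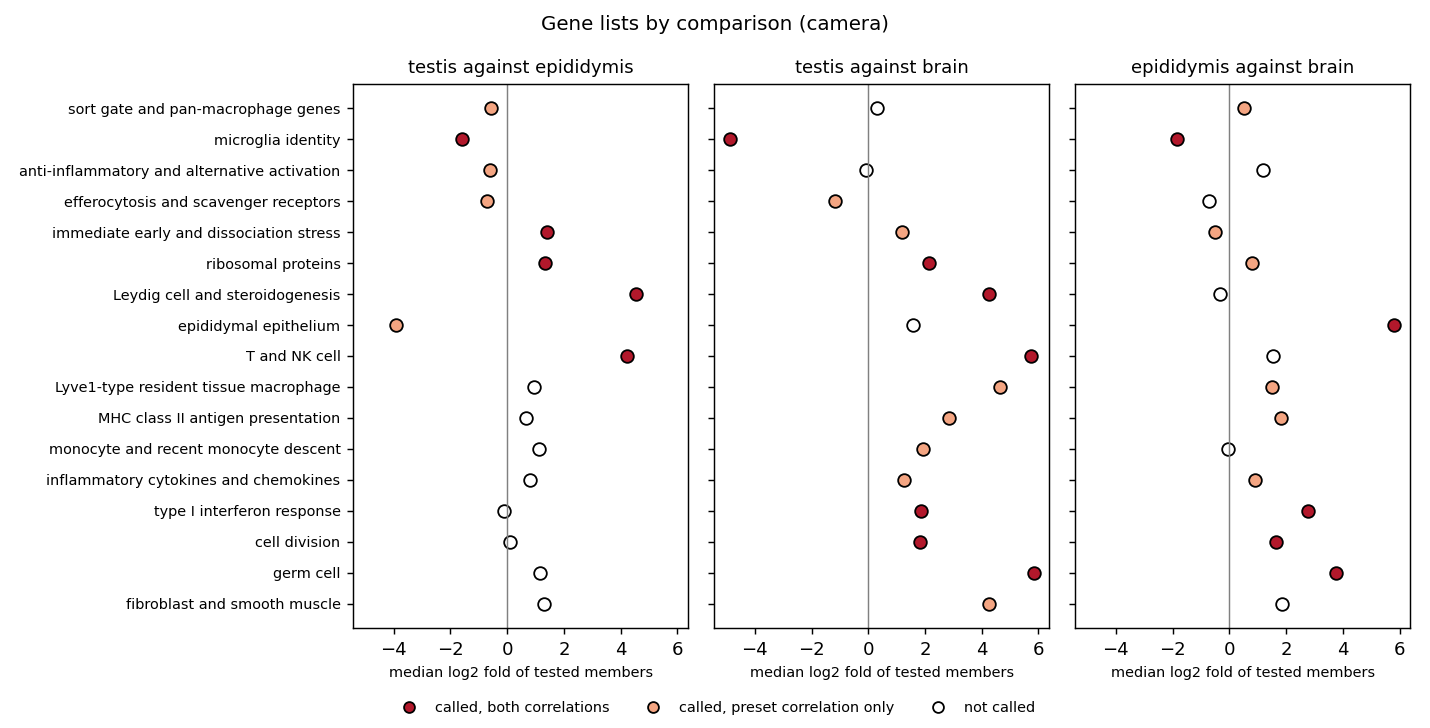
Median log2 fold of the tested members of the 17 gene lists called in at least 1 comparison, 1 panel per comparison, where the horizontal axis is the median and the fill gives the camera call with a preset and with an estimated correlation. Of 93 tests, 34 were called with the preset correlation, and 17 of these also with an estimated one, among them microglia identity in all 3 panels.

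Genes that set 1 organ apart from both others were most numerous for testis and brain. In testis, 227 genes were higher than in both other organs and 143 lower. Among the 227 were Ccr2, Mgl2 and Cd163l1, but also the Leydig list genes Insl3, Cyp17a1 and Hsd17b3 and the Sertoli list gene Defb19. Which cells gave the reads of these genes was not tested. Trem2 and Fcrls were among the 143. In epididymis 40 were higher, Defb20 among them, and 21 lower. In brain 138 were higher, among them Sall3, Slc2a5 and Siglech, and 271 lower, among them H2-Aa, Axl, Pf4 and Mrc1. Each set joins 2 comparisons that share the libraries of its organ. Independent lists, which leave that sharing out, would share 20 and 10.8 genes for testis and 6.67 and 5.28 for epididymis. Together 405 genes were higher in 1 organ than in both others. That total was 184 without the variance trend and lay between 220 and 317 when 1 library was left out: 262 without testis replicate 2, 261, 220 and 247 without epididymis replicate 1, 2 or 3, and 250 without brain replicate 1.

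Testis and epididymis shared many differences from brain. In the comparisons of testis and of epididymis with brain, 409 genes were called in the same direction, 271 higher and 138 lower, and 3 in opposite directions. Both comparisons use the same brain libraries. Simulations that drew all 9 libraries anew, brain included, with no gene changed gave a mean of 0.05 genes higher and 0.1 lower in both. Independent lists would share 24 and 10.2. The covariance of the log2 folds was 1.93, against 0.723 in the simulations, a difference of 1.21, but their correlation was 0.59 against 0.5 (highest 0.516), so most of the correlation also arose with no change. The simulated comparisons also shared their brain libraries, so 0.723 already holds the sharing at the spread that was drawn. With 3 brain libraries the controls could not be split into parts of at least 2. Part of the excess may still come from the shared controls, if the real brain libraries varied more than the drawn ones. The 409 shared calls were 239 without brain replicate 1, 247 without brain replicate 2 and 207 without the variance trend. Of the 223 genes higher in epididymis than in testis, 118 were also higher in brain than in testis with no call between epididymis and brain. In 23 genes all 3 differences were called in the order brain, epididymis, testis, and in 45 in the reverse order.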

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

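The tests of Leydig, germ cell, epididymal epithelium and T and NK cell transcripts, and the test for brain material in the epididymis libraries, were chosen only after the results were seen; the other tests of causes were written before.

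A total of 3 genes were called in both testis and epididymis against brain, in opposite directions. Klf4, a zinc finger transcription factor gene, stood at 6506 ± 1390 in testis, 1748 ± 159 in epididymis and 3712 ± 1530 in brain, a log2 fold of 1.878 between testis and epididymis (limma adjusted p = 0.00053, or 0.074 without the variance trend). Its opposite directions are weakly based. The limma adjusted p between testis and brain went from 0.035 to 0.54 after quantile normalization, 0.12 with the same total, 0.28 without the variance trend and up to 0.18 when a library was left out (brain replicate 1). Between epididymis and brain it went from 0.027 to 0.31 without the trend and to 0.14 without brain replicate 2. Pmepa1 stood at 445 ± 110, 6064 ± 294 and 2975 ± 693, a log2 fold of -3.794 between testis and epididymis (limma adjusted p = 4.4e-07), and its difference between epididymis and brain went from 0.012 to 0.24 without the trend and to 0.056 without epididymis replicate 3. Trpm2, a calcium channel gene, stood at 205 ± 62.5, 2192 ± 22.4 and 647 ± 49.0, a log2 fold of -3.465 (limma adjusted p = 4.1e-06), with 0.00088 between epididymis and brain, or 0.051 without the trend. Pmepa1 and Trpm2 were chosen after their values were seen.

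Transcripts of some other cell types differed by organ. The mean was highest in testis for 100% of the Leydig genes in the table (11 of 11) and for 100% of the T and NK cell genes (10 of 10), and highest in epididymis for 83.3% of the epididymal epithelium genes (15 of 18, of which 4 were tested), while 57.9% of germ cell genes (11 of 19) were higher in both testis and epididymis than in brain. Of every 10000 reads, astrocyte genes took 1.88 in brain, 0.682 in testis and 0.411 in epididymis. Their share was thus also highest in their organ, although the list was not called. Between testis and brain, 2 of 8 tested astrocyte genes were higher in testis (Aldoc and Aldh1l1) and 2 in brain (Slc1a3 and Aqp4). Per 10000 reads, neuron genes took 1.14 in testis and 0.917 in brain, and Sertoli cell genes 4.2 in epididymis and 2.07 in testis. Of 3 tested Sertoli genes, Defb19 was higher in testis than in epididymis, Trf was lower and 1 did not pass. These shares and counts restate the observation and decide no cause. The sort for CD45, CD11b and F4/80 was set to leave out Leydig, epithelial and most lymphoid cells, its purity was not analysed here, and whether RNA from other cells or the macrophages of the organ gave these values stays open.

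Ribosomal protein genes were higher in testis than in epididymis, with a median log2 fold of 1.32. Genes matched in transcript length had a median of 0.097 (95% interval -0.0126 to 0.23) and genes matched in GC content -0.0328 (-0.103 to 0.073), which argues against either bias as the cause. These intervals come from 1000 resamples of genes and do not measure the spread between libraries. The lower of the medians under other scalings was 1.04, which argues against the authors' scaling. RNA quality and handling might still differ by organ and were not tested, and a difference between the macrophages stays open.

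In 13 of 18 tested genes of the microglia list the means had the order testis, epididymis, brain, and of these 10 were called between testis and epididymis and 4 of those also between epididymis and brain, while Sall3, Slc2a5, Sparc and Sall1 stood at 1.52% of the brain level or less in epididymis. Material carried over from brain would give similar epididymis to brain ratios, but the lowest ratio was 0.8% of the highest, from 0.631% of the brain level for Sall3 to 78.9% for Bhlhe41, which argues against it as the only cause. The median log2 fold between testis and epididymis was -1.61 under the scaling that weakened it most, against -1.61 as deposited. A difference between the macrophages of the organs stays open and was not tested.

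Against chance, splits of the libraries of a pair of organs were too few for a share under 0.05. The real split was the 1 of 10 with the most calls in each comparison, at 516, 1371 and 564 genes, with 0 in the highest other split. Over the 3 organs, 100 splits were compared, the real one among them. Only the real one reached 1337 genes, and the highest other reached 346. Organ and mouse number coincide, so the splits cannot tell an effect of organ from one of mouse.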

How the results depend on the processing

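The tests with edgeR and DESeq2 on the recovered reads were chosen only after the results were seen, and all other alternatives were planned. Without the variance trend, calls fell from 516 to 192 (testis against epididymis), from 1371 to 837 (testis against brain), from 564 to 306 (epididymis against brain), from 1337 to 737 (any difference), from 405 to 184 (higher in 1 organ than in both others) and from 409 to 207 (shared against brain). Fitting only testis and epididymis gave 250 calls. DESeq2 gave 782 for testis against epididymis (443 higher and 339 lower) and 904 for epididymis against brain, while edgeR gave 366 and 458. Of 93 list tests, 34 were called with the preset correlation and 17 with an estimated one. Leaving out 1 library gave 278 to 442, 827 to 1457 and 320 to 597 calls in the comparisons, 859 to 1302 for any difference, 220 to 317 for genes higher in 1 organ, 239 to 377 for shared calls and 32 to 36 list calls. In testis against epididymis 193 of 516 calls were kept in all 9 leave-outs, in testis against brain 703 of 1371 and in epididymis against brain 235 of 564, and none changed sign. Of 81 other alternatives for these counts, 71 stayed within 1.5 times the main value. The 81 include rescaling by the median ratio for each count, which could change next to nothing. Rescaling to the same total left 534 and 1426 calls in the comparisons of testis, but moved the share higher in testis from 56.8% to 42.5% against epididymis and from 58.6% to 45.9% against brain, and quantile normalization moved the first to 46.6%. The median log2 fold of all tested genes between testis and epididymis was 0.10 as deposited and -0.05 with the same total. The Sertoli cell list, not called with camera and lower, was higher in testis than in epididymis with fry (limma, adjusted p = 3e-04). Jun, chosen after its values were seen, had a log2 fold of 0.18 between testis and brain that did not pass, and -0.998 after quantile normalization, which passed (limma adjusted p = 0.00029). Of 232 calls of named genes, 122 were kept in all 15 alternatives and 151 in all leave-outs. Both with the same total and after quantile normalization, 220 were kept, and all 232 kept their direction throughout. The cause of these shifts was not tested. No paired analysis was possible because the labels give no link between libraries of different organs. DESeq2 as planned for deposited counts did not apply.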

Other observations

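No test printed in this part was chosen after the result was seen, but Apoe and the genes with values near 0 in one replicate and high in another were.

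Apoe transcripts took a far larger part of the epididymis libraries than of the others. The log2 fold was -4.29 between testis and epididymis (limma adjusted p = 1.6e-06) and 7.05 between epididymis and brain (limma adjusted p = 4.6e-10), and both calls held under every alternative run for it. Runx3, a transcription factor gene of lymphocytes and some macrophages, stood at 652 ± 74.3 in testis, 463 ± 178 in epididymis and 46.9 ± 28.8 in brain. Srebf2, which drives cholesterol synthesis, stood at 370 ± 72.4, 72.6 ± 37.7 and 64.2 ± 36.2, with a limma adjusted p of 0.0067 between testis and brain and of 0.025 between testis and epididymis, or 0.1 without testis replicate 1. Spn, a sialoglycoprotein gene of leukocytes, stood at 1006 ± 380 in testis and 3.64 ± 5.55 in brain.

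Adamts1 was called in all 3 comparisons, at 149 ± 107 in testis, 0 in epididymis and 1832 ± 459 in brain. Ptgs1, which encodes cyclooxygenase 1, stood at 24.3 ± 24.8, 1085 ± 129 and 1512 ± 235, lower in testis than in brain (limma adjusted p = 0.00012) and than in epididymis (limma adjusted p = 9e-04, or 0.055 without the variance trend). Toll-like receptor genes were not called as a list (lowest limma camera adjusted p = 0.21), though Tlr3 was lower in testis than in brain, at 111 ± 40.7 and 467 ± 40.5, and Tlr2 was higher in epididymis than in brain, at 326 ± 131 and 52.1 ± 7.44.

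S100a8 and Csf3r, on the neutrophil list, were higher in brain, at 85.3 ± 21.1 and 259 ± 66.1, than in testis, at 0 and 6.10 ± 5.29. Of 5 tested neutrophil genes, 3 fell in testis against brain and 2 did not pass. Adjusted over the list alone, 3 fell and 2 rose. Bank1, on the B cell list, stood at 263 ± 93.1 in brain and 2.55 ± 3.74 in testis, and the other 5 tested members did not pass. As lists, neutrophil and B cell genes were not called (lowest limma camera adjusted p = 0.18 for both). Further lists not called were those for cholesterol synthesis (lowest limma camera adjusted p = 0.067), astrocytes (0.14), mitochondrially encoded genes (0.22), sex-linked genes (0.32), Sertoli cells (0.47), neurons (0.49), endothelial cells (0.51), dendritic cells (0.6), macrophage transcription factors (0.84), oligodendrocytes (0.96) and growth factors (0.98).

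Some genes were near 0 in one replicate and high in another of the same organ. The mitochondrial genes COX2 and ATP6 stood at 4.14, 3164 and 4875, and at 2.07, 1.62 and 2185, in testis replicates 1, 2 and 3. Values of at most 10 beside at least 500 within an organ occurred for 3 genes in testis, 5 in epididymis and 2 in brain, Rps6 and Pltp among them.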
